A study of Mus musculus with 8 samples.

How the data were processed

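Smad4 binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse CD4+ T cells from spleen and lymph nodes of C57BL/6 animals. The cells were activated and kept for 12 h with interleukin 6 and an inhibitor of the TGF-β receptor. There were 2 wild-type (WT) and 2 Smad4 knockout (KO) ChIP samples, and 4 input samples (chromatin without immunoprecipitation), for 8 samples in all. In the KO animals a Cre recombinase active in T cells removes a floxed Smad4 allele.

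Each ChIP sample came with a list of called peaks, deposited by the authors as chromosome, start and end, without a height, fold enrichment, p-value or score. The submitters' processing notes name Trim Galore, Bowtie and HOMER 4.8.3 and the mouse build mm10, without giving the role of each. Peak lists were given per sample, so replicates were not pooled in them. Thresholds, filters, the use of the input samples in calling and the number of reads per sample are not given in the sources used here. Signal tracks and the input samples were not analysed here. With the read depth unknown, a gap between lists in peak number can follow depth as well as binding.

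Positions are 1-based, on mm10. Gene bounds were taken from a RefSeq table on GRCm38.p6, the same assembly. Of its 21896 protein-coding genes, 21775 were used; genes starting below 3 Mb on chromosomes other than Y were left out, because scaffold coordinates stand there under a chromosome name. The table gives neither strand nor exons. A planned split into promoters, exons and introns was therefore replaced by 3 classes of the region centre: within 1 kb of either end of a protein-coding gene (called a gene end here), elsewhere inside a gene, or outside genes. The planned territory of a gene, its body and 10 kb upstream, was replaced by the body and 10 kb on both sides. The nearest gene stood in for the nearest transcription start site. A planned count of 18 sequence motifs was not run, since no genome sequence was used here.

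Peaks that met by at least 1 bp were merged. A reproducible WT region holds a peak of both WT lists, and a WT-only region is a reproducible WT region that meets no peak of either KO list. Overlaps were compared with 1000 circular shifts of one list along its chromosomes, with a 1-sided permutation p, whose smallest possible value is 0.001. Shares of regions per location class were compared with 1000 shifts in the same way, 2-sided, with a smallest p of 0.002. Local shifts of 20 to 100 kb, which keep regions in their chromosomal neighbourhood, were added after the data were seen. Intervals of shares are exact 95% Clopper-Pearson intervals; they cover counting error only, since neighbouring peaks are not independent. Peak number, covered length and mean width were compared between WT and KO by a 2-sided exact permutation test of log10 values. With 2 samples against 2, its smallest p is 0.333.

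The 12 gene lists, with 172 distinct genes, were fixed before the data were examined, as were the comparisons and the rule for naming genes. All 172 were found in the gene table. For each list, the number of genes with a WT-only region in their territory was compared with 10000 random lists of protein-coding genes, matched on 10 groups of territory length. The 2-sided permutation p, at least 0.0002, was adjusted by Benjamini-Hochberg over the 12 lists. The test was checked with drawn gene lists on the reproducible WT regions, not on the WT-only regions. Of 500 random lists of 15 genes, 2.4% were called at an unadjusted threshold of 0.05. Of 200 lists built to hold 13 of 16 bound genes, 99.5% were called at that threshold, a share of bound genes that made a call likely in advance.

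The rule for named genes took Smad4, Cd4, Il17a, Il17f, Ski and Skil whatever they showed, up to 4 genes per list, the 10 top WT-only regions and the 5 top regions called in both KO lists. Without a score, the rule ranked regions by the summed width of their peaks in the 2 lists. Other genes named, such as list members without a region, were chosen after their values were seen. Some genes that the rule takes are not reported here. Alternatives were an overlap of 50% of both peaks, centres within 100 bp, autosomes only, no KO peak within 1 kb, gene ends of 5 kb, assignment by nearest gene within 100 kb or by gene end, leaving out each list, and pairing by replicate number. The upper part of each list by score was replaced by the upper part by width. For location classes and gene lists, the wider peaks mean the upper part of the WT-only regions by summed peak width. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1; figures used matplotlib 3.10.9.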

Results

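Smad4, the SMAD protein shared by TGF-β and BMP signalling, was profiled by ChIP-seq in activated CD4+ T cells held for 12 h with interleukin 6 and a TGF-β receptor inhibitor. The study's title places the experiment in the restraint of Th17 differentiation by SKI and SMAD4. These samples show where Smad4 was detected in the presence of the inhibitor. How far TGF-β signalling was blocked was not measured here. The KO libraries serve as the control for antibody background in cells meant to lack Smad4, although Smad4 remaining in them was not excluded. There were 2 WT and 2 KO libraries, each with its own list of peak positions on mm10. Both WT samples were labelled female, KO replicate 1 a pool of both sexes and KO replicate 2 male, so sex and genotype were not separated. Beyond these sexes, the labels do not say whether replicates came from separate animals, so comparisons between groups describe these samples only. Read depth was unknown.

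Ski, which encodes a co-repressor that binds SMAD proteins, held peaks in both WT libraries and none in either KO library. The same held for the interleukin genes Il17a and Il17f and for Cd4. Such a pattern did not set these genes apart. Of the 21775 protein-coding genes, 9655 had a WT-only region in their territory, and 526 had a region called in a KO library. Genome-wide, WT replicate 1 had 27120 peaks and WT replicate 2 had 19792, against 564 in KO replicate 1 and 424 in KO replicate 2. The mean was 23456 ± 5182 peaks (SD, n = 2) in WT and 494 ± 99.0 (SD, n = 2) in KO, a 47.4-fold difference between geometric means. WT peaks covered 13.5 ± 3.22 Mb and KO peaks 163 ± 42.5 kb (SD, n = 2 each), an 82.8-fold difference. Mean peak width was 573 ± 10.8 bp in WT and 328 ± 20.1 bp in KO (SD, n = 2 each), which is 1.75-fold. For each of these measures both WT values lay above both KO values, and the exact permutation test gave p = 0.333, the smallest that 2 against 2 allows. Many peaks stood at the smallest width of their list, which was 240 and 242 bp in WT and 254 and 234 bp in KO. These were 19.0% and 19.4% of the peaks in WT replicates 1 and 2, and 48.0% and 40.3% in KO replicates 1 and 2. Mean width, above all in KO, therefore partly reflects this floor.

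**Figure D1:**
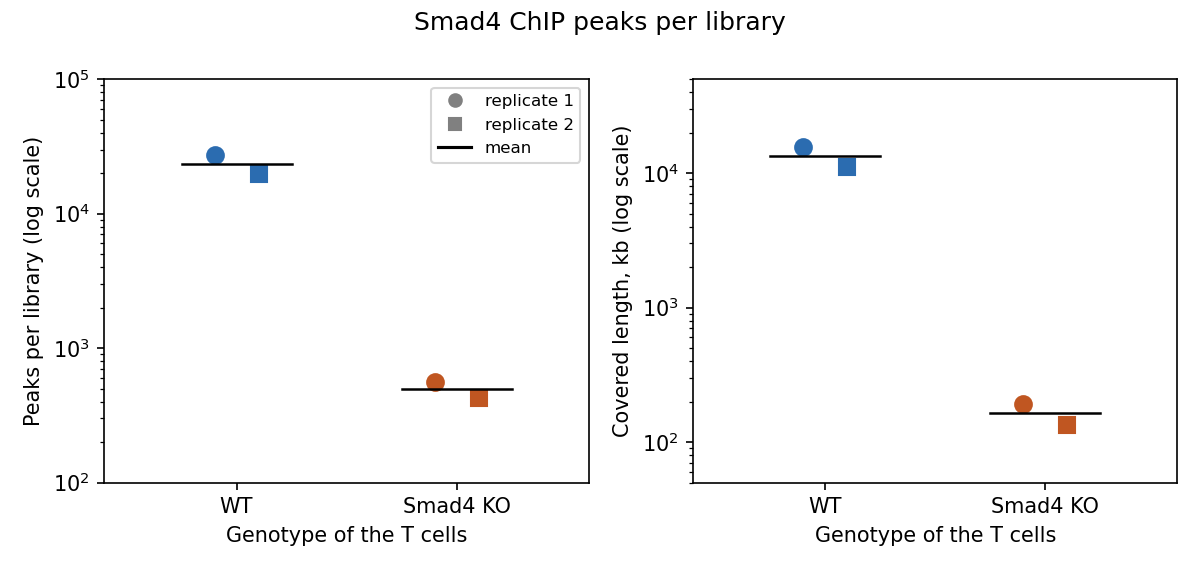
Number of Smad4 peaks (left) and covered length in kb (right) per library, on log axes, for WT and Smad4 KO T cells; each point is one library and the line is the group mean. The WT libraries had 27120 and 19792 peaks, and the KO libraries 564 and 424.

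Il17a and Il17f, which encode the signature cytokines of Th17 cells, each had 1 WT-only region outside the gene. The Il17a region (chromosome 1, 20740385 to 20741111) lay 5.89 kb from the gene and the Il17f region (20791380 to 20791907) 6.11 kb from it. Ski (chromosome 4, 155154075 to 155222535) held 10 WT-only regions, from 12 peaks in WT replicate 1 and 11 in WT replicate 2. Skil, which encodes the related co-repressor SnoN (chromosome 3, 31095058 to 31122923), held 5 WT-only regions and 1 region of 5148 bp over its start coordinate that was also called in both KO libraries. Cd4 (chromosome 6, 124864693 to 124888247) held 2 WT-only regions, one of them inside the gene at 124885125 to 124885629. Smad4 itself (chromosome 18, 73634790 to 73703791) held 3 reproducible WT regions. The region at 73703546 to 73704200, over a gene end, and the region at 73643046 to 73643489 were WT-only, and the region at 73680513 to 73681006 was also called in KO replicate 1. Peak positions do not show whether the Smad4 allele was deleted.

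**Figure D2:**
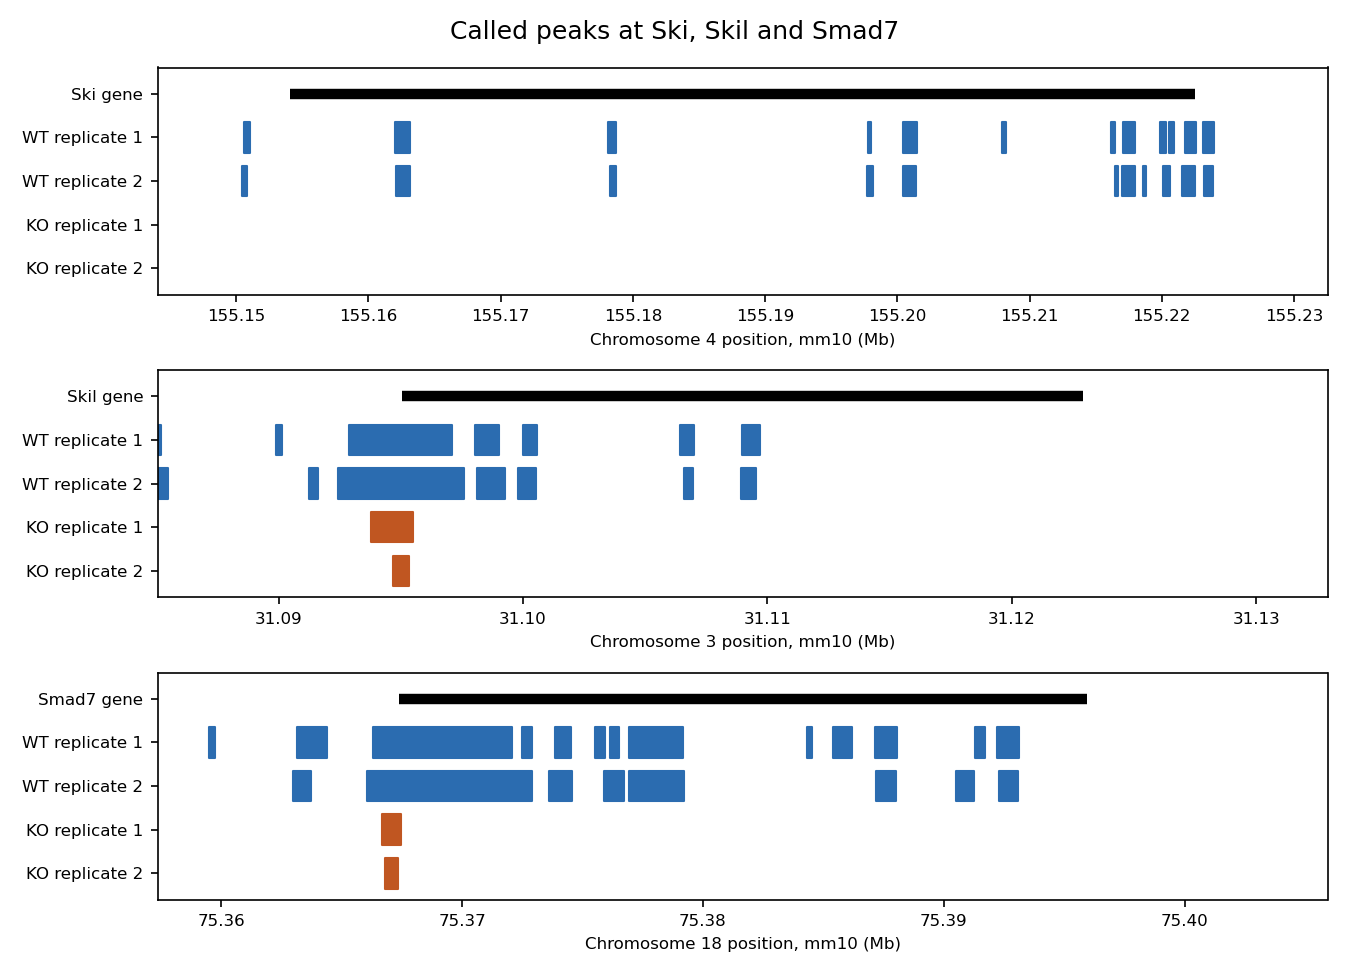
Called peaks (boxes) in the 4 libraries around Ski, Skil and Smad7; the horizontal axis is the mm10 position in Mb and the black bar is the gene. Ski had peaks in WT libraries only, while Skil and Smad7 each had 1 region that was also called in both KO libraries.

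The WT lists shared most of their peaks. Of the peaks of WT replicate 2, 85.8% (16983 of 19792; interval 85.3% to 86.3%) met a peak of WT replicate 1, and 61.5% (16678 of 27120; 60.9% to 62.1%) did so in the other direction. Circular shifts gave means of 1.28% and 0.937%, and local shifts, which keep the chromosomal neighbourhood, 4.59% and 3.36% (permutation p = 0.001 for each, the smallest possible). Merging gave 16501 reproducible WT regions, of which 15882 (96.2%) met no KO peak; these WT-only regions covered 12.6 Mb and had a median width of 644 bp. They fell in the territory of 9655 of the 21775 protein-coding genes (44.3%). The widths of the WT peaks in a region had a Spearman correlation of 0.715 across the 16501 regions, which are not independent replicates. Without WT replicate 2 the WT-only set rested on a single list and grew to 26463 regions.

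The widest WT-only region by summed peak width lay at Junb, an AP-1 transcription factor gene (chromosome 8, 84974492 to 84980465), and had peaks of 5974 and 3766 bp in WT replicates 1 and 2. It spanned the whole of Junb and also met Prdx2. The immediate-early gene Ier2 followed (chromosome 8, 84658587 to 84665311), with peaks of 6158 and 3538 bp. Regions over a gene end followed at the transcription factor gene Klf13 (chromosome 7, 63936242 to 63940957), at Trim8 (chromosome 19, 46499326 to 46503678) and at the kinase gene Pim1 (chromosome 17, 29489201 to 29493278). The region at Zfp36l2, which encodes an RNA-binding protein (chromosome 17, 84184940 to 84188845), had its centre inside the gene. Nr4a3, an orphan nuclear receptor gene (chromosome 4, 48042363 to 48046314), and Socs1, a feedback inhibitor of cytokine signalling (chromosome 16, 10781955 to 10786891), also held one of the top 10 regions. The remaining 2 lay inside Zfp827 (chromosome 8, 79027547 to 79031566) and at a gene end on chromosome 15 (96284764 to 96288819), where the region met Gm38469 and Arid2.

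Peaks that remained in KO libraries lay mostly on WT regions. The widest region called in both KO libraries was at Skil (chromosome 3, 31093768 to 31095483), with peaks of 1716 bp in KO replicate 1 and 668 bp in KO replicate 2, inside the WT region of 5148 bp. The next lay inside Kdm6b, a histone demethylase gene (chromosome 11, 69410366 to 69411965), with peaks of 1554 and 416 bp. Others lay 123 kb from Smim20 (chromosome 5, 53401707 to 53402770), 3.60 kb from Ankrd12 (chromosome 17, 65961385 to 65962100) and inside Alpk2 (chromosome 18, 65322165 to 65322927). All 5 met a reproducible WT region. Smad7, which encodes an inhibitory SMAD, had a region (chromosome 18, 75366053 to 75372921) called in all 4 libraries. Of all KO peaks, 83.2% (822 of 988; interval 80.7% to 85.5%) met a reproducible WT region, 83.3% in KO replicate 1 and 83.0% in KO replicate 2, against a mean of 0.774% under circular and 3.17% under local shifts (permutation p = 0.001 for each). Requiring 50% of both the peak and the region lowered this share to 14.98%, a rule that narrow KO peaks in wide WT regions cannot meet, and centres within 100 bp lowered it to 58.8%.

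The KO lists shared 34.6% of the peaks of KO replicate 1 (195 of 564; interval 30.7% to 38.7%) and 46.2% of those of KO replicate 2 (196 of 424; 41.4% to 51.1%). Circular shifts gave means of 0.0111% and 0.0175%, and local shifts 0.117% and 0.161% (permutation p = 0.001 for each, the smallest possible). Of the 195 regions called in both KO lists, 192 met a reproducible WT region. Of the 16501 reproducible WT regions, 619 (3.75%) met a KO peak, 193 of them peaks of both KO lists. With the reproducible WT regions in 10 groups by peak width, 0.485% of the narrowest group met a peak of KO replicate 1 and 0.242% a peak of KO replicate 2. In the widest group these shares were 8.96% (interval 7.63% to 10.4%) and 6.48% (5.34% to 7.78%).

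**Figure D3:**
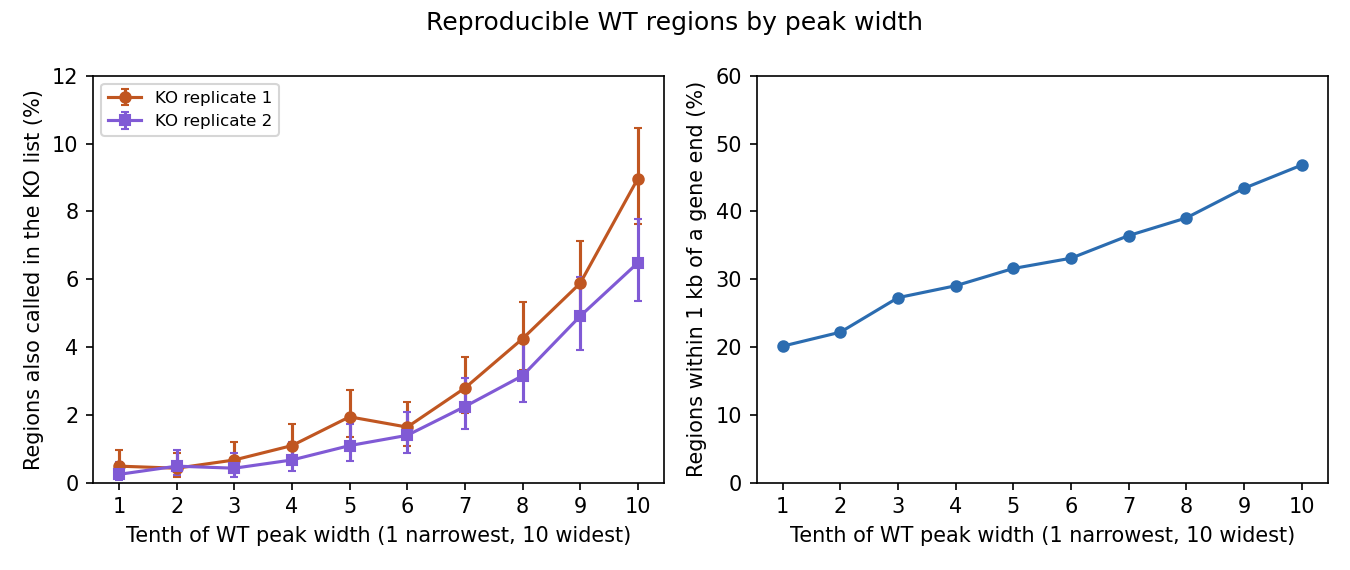
Reproducible WT regions in 10 equal groups by WT peak width (horizontal axis, 1 narrowest, 10 widest). Left, the percent also called in each KO library with exact 95% intervals, which reached 8.96% and 6.48% in the widest group; right, the percent with a centre within 1 kb of a gene end, which went from 20.1% to 46.8%.

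WT-only regions were concentrated at gene ends, as at Bcl6, Rel and Bcl11b, where the widest WT-only region overlapped an end of the gene. Of the 15882 WT-only regions, 33.7% (interval 32.9% to 34.4%) had their centre within 1 kb of a gene end, against a mean of 3.21% under circular and 6.06% under local shifts. Outside genes lay 28.1%, against 57.3% under circular shifts (permutation p = 0.002 for both classes against circular shifts, the smallest possible). The share elsewhere inside genes, 38.3%, did not differ from the shifts at the threshold (mean 39.5%, permutation p = 0.230). Of the 792 regions called in either KO library, 12.0% (interval 9.81% to 14.5%) lay at a gene end, and the highest of the 1000 shifts gave 4.97% (permutation p = 0.002). WT-only regions lay at gene ends more often than KO regions (odds ratio 3.72, Fisher's exact test, p = 7.6e-43), a test that compares these lists and takes neighbouring regions as independent. The share at gene ends was 13.5% in KO replicate 1 and 7.78% in KO replicate 2.

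Among the 12 gene lists, 6 had more genes with a WT-only region than random lists of the same gene lengths, 2 had fewer, and 4 did not pass the test. Random genes were not matched on activity in these cells, so the calls do not separate a pathway from active genes in general. Ribosomal protein genes, tested after the data were seen, also lay above random lists, with 68 of 87 bound. Genes of the TGF-β/SMAD pathway were bound in 24 of 27 cases, against 13.5 in random lists (adjusted permutation p = 0.0006). Tgif1, a homeobox co-repressor gene, had the widest WT-only region of this list by summed peak width (chromosome 17, 70848908 to 70853968; peaks of 4872 and 2326 bp in WT replicates 1 and 2). It was followed by Pmepa1, which encodes a membrane inhibitor of SMAD signalling (chromosome 2, 173273631 to 173277172; 5 WT-only regions). Smad6, an inhibitory SMAD gene, held 3 WT-only regions and Smad7 held 6. The receptor gene Tgfbr2 held 7 and Smad3 held 10, while Ltbp3 and Acvr1 were among the genes without a WT-only region. In 6 genes of the list a KO library also had a region. Over all 21775 protein-coding genes, 526 had such a region, a smaller share than in this list. Of the 12 lists, only the B cell, hepatocyte and neuron lists had no gene with a KO region. All other lists had a larger share than all genes together. KO regions thus fell on many of the same lists as WT-only regions. These KO counts were not tested or matched on gene length.

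All 14 genes of the IL-6/STAT3 list had a WT-only region, against 6.97 in random lists (adjusted permutation p = 0.0006). Besides Pim1 and Socs1, the widest WT-only regions lay at Bcl6, a transcriptional repressor gene (chromosome 16, 23986603 to 23989782), and 3.65 kb from Il6st, which encodes the shared signalling receptor gp130 (chromosome 13, 112457909 to 112460424). Stat3 held 4 WT-only regions, Il6ra 10 and Jak1 15. A KO library also had a region in 4 genes of the list, Pim1 and Stat3 among them. In the Th17 list, 13 of 16 genes had a WT-only region, against 7.87 in random lists (adjusted permutation p = 0.0372), and 4 had a region in a KO library. The widest WT-only regions lay at Irf4 (chromosome 13, 30746927 to 30749931), Nfkbiz (chromosome 16, 55819957 to 55822725), Rora (chromosome 9, 69071959 to 69073904) and Hif1a (chromosome 12, 73907120 to 73909583), all genes of transcriptional regulators. The Th17 genes without a WT-only region were Il23r, whose reproducible region was called in KO replicate 2, Ccr6, with 3 peaks in WT replicate 1 alone, and Il22, with none. With regions counted within 1 kb of a gene end, 7 Th17 genes were bound and the list no longer passed the test (adjusted permutation p = 0.541; range over all alternatives 0.0008 to 0.541).

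The T cell identity list had a WT-only region at all 19 genes, against 9.61 in random lists (adjusted permutation p = 0.0006). Ets1, a transcription factor gene of lymphocytes, held 24 WT-only regions, Bcl11b 16, Lef1 12 and Runx1 9. No KO peak lay in the territory of Ets1, Bcl11b or Lef1. KO replicate 2 had 2 peaks at Runx1, and each KO library had 1 at Cd247. The activation list, with AP-1, NFAT and NF-κB genes, was bound in 18 of 20 genes, against 8.93 (adjusted permutation p = 0.0006); the exceptions were Batf3 and Irf8. Its widest WT-only regions lay at Junb and Nr4a3, 4.41 kb from Egr1 (chromosome 18, 34853963 to 34856792) and at Rel (chromosome 11, 23769535 to 23771812). A KO library had a region in 5 genes of this list. In the regulatory T cell list, 10 of 12 genes were bound, against 5.87 (adjusted permutation p = 0.0435), and 3 had a region in a KO library. By width of the widest WT-only region, the receptor gene Il2ra led, with 9 WT-only regions and 3 further regions that were also called in KO. Tnfrsf18 followed with 5 WT-only regions, Tnfrsf9 with 3 and Ctla4 with 3, while Nrp1, with narrower regions, held 7. The regulatory T cell call ended without KO replicate 2 (adjusted permutation p = 0.0504) and with the gene-end rule (6 genes, adjusted permutation p = 0.419; range over all alternatives 0.0104 to 0.419).

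**Figure D4:**
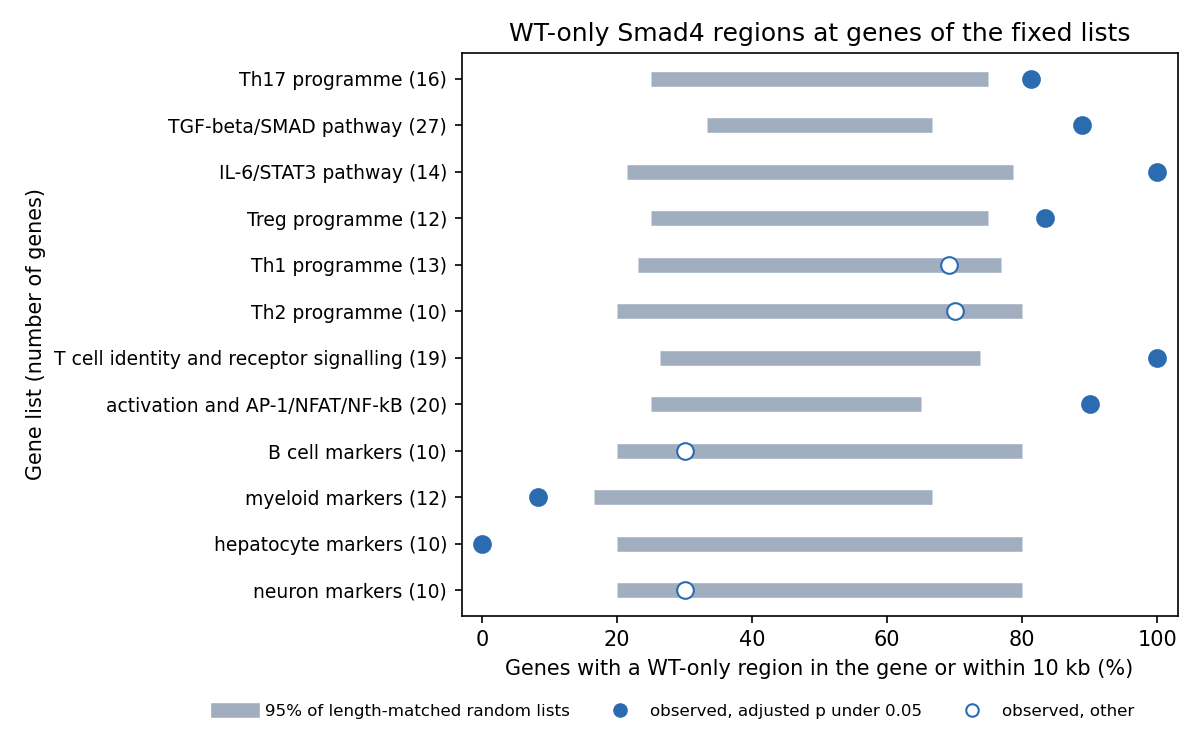
Percent of genes in each fixed list with a WT-only Smad4 region in the gene or within 10 kb of it (points; filled where the adjusted p was under 0.05), beside the central 95% of random lists matched on gene length (bars). The T cell identity and IL-6/STAT3 lists stood at 100%, and the hepatocyte list at 0%.

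The Th1 list had 9 of 13 genes with a WT-only region, against 6.09 (adjusted permutation p = 0.234), and the Th2 list 7 of 10, against 4.64 (adjusted permutation p = 0.282). In the Th1 list the widest WT-only region lay 2.06 kb from Eomes, where the peaks were 1988 and 242 bp wide in WT replicates 1 and 2, and another lay inside Runx3. Tbx21, the defining Th1 factor gene, had 4 peaks in WT replicate 1 and none in WT replicate 2. The Th1 list passed the test when regions were assigned to the nearest gene (11 genes, adjusted permutation p = 0.0008) and without WT replicate 2 (13 genes, adjusted permutation p = 0.0028); over all alternatives the values ran up to 0.419. In the Th2 list, WT-only regions lay 5.63 kb from Stat6 (chromosome 10, 127666614 to 127669273), at Nfil3, 0.335 kb from Ccr8 and inside Gata3, while the cytokine genes Il4, Il5 and Il13 had none.

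Of the 4 lists of other cell types, the hepatocyte and myeloid markers lay below the random lists. No hepatocyte gene of 10 had a WT-only region, against 4.71 in random lists (adjusted permutation p = 0.0134), and 1 myeloid gene of 12, Fcgr1, did, against 4.99 (adjusted permutation p = 0.0398). The B cell list had 3 of 10, against 4.50 (adjusted permutation p = 0.531), with 5 WT-only regions at Cd79a and 1 each at Pax5 and Vpreb3. The neuron list also had 3 of 10, at Syn1, Slc17a7 and Rbfox3, against 5.14 (adjusted permutation p = 0.313). The myeloid call ended without WT replicate 1 (3 genes, adjusted permutation p = 0.3298), without WT replicate 2 (6 genes, adjusted permutation p = 1), without KO replicate 2 (2 genes, adjusted permutation p = 0.173) and with the nearest gene (1 gene, adjusted permutation p = 0.143), the gene-end rule (0 genes, adjusted permutation p = 0.0880) or the wider peaks (1 gene, adjusted permutation p = 0.275). The hepatocyte call ended with the gene-end rule (adjusted permutation p = 0.0880) and with the wider peaks (adjusted permutation p = 0.101), where its count was also 0; the lowest value over all alternatives was 0.0028.

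The X chromosome held a smaller share of the peaks than of the annotated length. WT replicate 1 had 413 peaks on X (1.52%; interval 1.38% to 1.68%) and WT replicate 2 had 335 (1.69%; 1.52% to 1.88%), while X makes up 6.30% of the annotated span. The KO libraries had 5 peaks each on X (0.887% and 1.18%). Of the X-linked protein-coding genes 174 of 963 (18.1%) had a WT-only region, against 9480 of 20556 autosomal genes (46.1%). Foxp3 and Cxcr3, both on X, each held 2 WT-only regions. On Y there were 3 peaks in WT replicate 1, 2 in WT replicate 2, 2 in KO replicate 1 and none in KO replicate 2. No test was run on these shares, and sex differed between the groups.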

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

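Of 58 alternative values of the main comparisons, 54 kept their direction and their side of the threshold or stayed within the set limits; local shifts and the wider peaks were chosen after the data were seen. The p of 0.333 could not have passed in any of them, and some folds could not move by construction: that in peak number when the same share of each list was kept, and both folds when paired. The fold in peak number ranged from 40.5 to 55.5 and that in covered length from 68.7 to 99.7 when one library was left out. Pairing WT and KO by replicate number, which the labels do not tie to shared animals or days, gave 47.4-fold for peak number (48.1 and 46.7 in the pairs) and 82.8-fold for covered length (81.5 and 84.1), with an exact sign-flip p of 0.5, and changed no call. With the wider peaks of each WT list there were 8063 WT-only regions, and leaving out one library gave 16037 to 26463, the highest without WT replicate 2, when a single list defines the set; both shifts follow from how many peaks enter. The Spearman correlation of WT peak widths was 0.857 with 50% overlap, where only peaks of similar extent can pair. With regions within 1 kb of a gene end, 4 gene lists passed the test in place of 8, and the Th1 and Th2 lists, with 2 and 3 bound genes, lay below the random mean without being called; the cause was not tested. Of 84 values for single lists, 69 kept their direction and call, 11 lost the call, 2 gained it and 2 turned. The calls of the TGF-β/SMAD, IL-6/STAT3, T cell identity and activation lists held in all 7 alternatives run for them. The motif comparison, the alternatives by score and those by transcription start site were not run. Read depth and peak height limit every peak list, and with the depth unknown they may limit the KO lists more than the WT lists. A region without a call is not shown to be unbound.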

Other observations

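The tests of gene families, of regions per gene, of matched regions, of local shifts and of positions on Y were chosen only after the results they bear on were seen. Among 15 families picked by gene symbol, ribosomal protein genes had a WT-only region in 68 of 87 cases, against 29.7 in length-matched random lists (adjusted permutation p = 0.0006), with 4 regions at Rpl13a. The Kdm histone demethylases followed with 16 of 18, against 9.80 (adjusted permutation p = 0.0100), including 5 regions at Kdm2b. Chemokine receptors were bound in 14 of 19 cases, against 8.05 (adjusted permutation p = 0.0251), with 8 regions at Ccr7, the receptor that guides T cells into lymph nodes, and 6 at Cxcr5. Guanylate-binding protein genes, which interferon induces, were bound in 9 of 10, against 5.04 (adjusted permutation p = 0.0390). Families of other tissues lay below the random lists: olfactory receptors with 12 of 1109, against 159, vomeronasal receptors with 2 of 352, against 92.9, keratins with 6 of 53, against 22.5, and cytochromes P450 with 14 of 99, against 48.8 (adjusted permutation p = 0.0006 for each), and Hox genes with 7 of 39, against 15.5 (adjusted permutation p = 0.0146). Dual-specificity phosphatases (14 of 24), Krüppel-like factors (12 of 17), interferon regulatory factors (6 of 9), SOCS and CISH genes (6 of 8), TNF receptors (14 of 20) and interleukin receptors (23 of 41) did not pass the test. Genes of a family often lie side by side, so 1 region can count for several of them, and 1 stretch without regions can leave many without any. The random lists were drawn without regard to position, so these p-values take neighbouring genes as independent.

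The protein-coding genes with the most WT-only regions were Foxp1 with 39, Bach2 with 33, Inpp4b with 31, Prkch with 25 and Ets1 with 24. These counts were not matched on gene length, and longer genes can catch more regions. Foxp1 spans 597 kb, Bach2 348 kb, Inpp4b 792 kb, Prkch 193 kb and Ets1 122 kb. Foxp1 and Bach2 encode transcription factors that help keep T cells quiescent. Ubac2 had 22, of which its neighbour Gpr183 inside the same territory shared 7. Tg, the thyroglobulin gene, had 20, and the nested gene Sla, which encodes an adaptor of T cell receptor signalling, had 11.

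KO peaks lay on WT regions in 83.2% of cases, and none of 1000 local shifts of the WT regions came above 5.71%, so chance overlap with long lists was excluded. KO-called WT regions were less often at gene ends, 13.4% (interval 10.8% to 16.3%), than WT regions of the same width (mean 39.4%, central range of the draws 35.9% to 43.1%). The share was 15.3% for KO replicate 1 and 7.47% for KO replicate 2. Filters and input use in peak calling are unknown. A filter applied alike to all libraries could have removed weak peaks at gene ends. The gap therefore does not decide on background from open chromatin at gene ends, and open chromatin elsewhere was not tested. Matching on the order of peaks in the lists gave a mean of 39.2%. For the same reason, this does not decide whether Smad4 remained in the same proportion at gene ends and elsewhere. Width and order also only stand in for peak height. The KO-called share was higher in the widest of 10 width groups than in the narrowest both away from gene ends, 15.6% (13.3% to 18.2%) against 0.835% (0.417% to 1.49%), and at gene ends, 5.56% (4.05% to 7.42%) against 0% (0% to 1.10%), so this contrast does not separate remaining Smad4 from any other signal that grows with region width. Remaining Smad4, background from open chromatin and an antibody that also binds another protein at these sites stay open. On autosomes alone 83.9% of KO peaks met a reproducible WT region, so peaks on X and Y do not account for the overlap. Other effects of the difference in sex between the groups were not separated.

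Genes of the TGF-β/SMAD list held 90 WT-only regions in cells kept with the receptor inhibitor. Random bound genes of the same length held 49.4 (central range 35 to 70, adjusted permutation p = 0.0056 over 8 lists). Gene length and being bound at all therefore do not account for the number. The surplus was not particular to this pathway: T cell identity genes held 133 distinct regions (136 with regions shared by neighbouring genes counted for each), against 38.3, IL-6/STAT3 genes 62, against 24.4, and activation genes 68, against 29.9 (adjusted permutation p = 0.00053 for each). Th17 genes held 49, against 24.0 (adjusted permutation p = 0.0112), regulatory T cell genes 40, against 20.1 (adjusted permutation p = 0.0283), and Th2 genes 21, against 11.7 (adjusted permutation p = 0.0267), while Th1 genes held 18 distinct regions (19 counted per gene), against 17.1 (adjusted permutation p = 0.764). The other lists shared no region between genes. A hypothesis is that Smad4 may gather at genes active in these cells with or without TGF-β input. No expression values or cells without the inhibitor were analysed here to test it.

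All 5 peaks on Y in the WT libraries, labelled female, lay within 1 Mb of the last annotated position of Y. Sequence that Y shares with X at its far end could give such reads. The bounds of that sequence were not used here, so the window does not separate it from Y sequence beside it. The 2 peaks on Y of KO replicate 1, from a pool of both sexes, lay at 145593 to 145846 and 258548 to 258801, far from the last annotated position. WT replicate 1 also had 3 peaks, of 2598, 670 and 1120 bp, between 39843469 and 39848960 on chromosome 17, around the ribosomal RNA gene Rn18s-rs5, where WT replicate 2 had 1 of 242 bp and the KO libraries none.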
